A study of Homo sapiens with 30 samples.

How the data were processed

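Chromatin accessibility was measured by Omni-ATAC-seq, an assay in which the Tn5 transposase inserts sequencing adapters into open DNA, with Nextera reagents. The 30 libraries came from LNCaP and VCaP, 2 established human prostate cancer cell lines that respond to androgen. Per the labels, the cells spent 48 hours in medium with 8% charcoal-stripped serum, which is low in steroid hormones, and then 24 hours with vehicle or with R1881, a synthetic androgen. LNCaP received 0.03, 0.06, 0.1 or 10 nM (replicates numbered 3, 4 and 5) and VCaP received 0.01, 0.03, 0.06 or 10 nM (replicates numbered 1, 2 and 4). Each of the 5 groups per line held 3 libraries, and every library's line, dose and replicate number came from its label.

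The submitters' processing notes name Trimmomatic 0.39, BWA 0.7.17, MACS2 2.2.7.1 and deepTools 3.5.1, with the genome build GRCh38 (hg38). The deposited files hold 1 peak list per library, with peaks split at several summits where MACS2 found them. The score that the authors deposited for each peak is 10 times its −log10 p, cut to a whole number. The deposited signal value is a ratio, the fold enrichment of the summit over the peak caller's local background in the same library. The authors' lists also give the −log10 p and the −log10 q of each summit. A further deposited column gives the summit's offset in bp. No column held contradicting values when each was checked against these units.

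All libraries were scored on 1 set of 443798 regions, which are windows reaching 250 bp to either side of a peak summit. Windows were placed on the summits of all libraries, strongest first, and did not overlap. Lists differed in length, so each was shortened to the shortest list of its line, 134750 entries in LNCaP and 104726 in VCaP, keeping the highest −log10 p. A region's value in a library is the percentile rank, by −log10 p, of the best peak overlapping it by at least 1 bp, on a scale from 0 to 100. A region without a peak has the value 0, so a value of 0 means not listed, and a difference is in percentile points. A rank shows a peak's place within its own library and not its absolute signal.

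Regions with a peak in at least 3 of a line's 15 libraries were tested, 186870 in LNCaP and 141802 in VCaP. limma 3.58.1 in R 4.3.3 fitted group means over the 15 libraries of a line, with a trend and robust moderation of the variance. A region was called at a Benjamini-Hochberg adjusted p under 0.05, and all tests were two-sided. The contrasts were each dose against vehicle, 10 nM against the mean of the 3 low-dose groups, and the low doses against vehicle. A fit over all 30 libraries tested whether the change at 10 nM differed between the lines, at 107845 regions that passed the filter in both. The contrasts, tests, gene lists, named-gene rule and most alternatives were fixed before the data were examined.

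The peak lists hold no read counts, so the number of reads per library is unknown, and no counting interval can be given. Relative depth was recovered by solving each peak's fold enrichment and −log10 p for the summit pileup and its local background under a Poisson model. The solved pileups lay within 0.05 of a whole number for 100% of the solved peaks in every library. A library's background pileup is percentile 1 of its solved backgrounds. Where limma was fitted to summit pileups, their log2 values were first centred on each library's median over the regions tested. The lists end at the authors' threshold, so a region at 0 may hold signal below it.

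Regions were assigned to the nearest protein-coding gene body within 100 kb, with RefSeq gene positions on GRCh38.p14. The plan had named transcription start sites, but the annotation used here gave no strand, so "gene end" below stands for either end of a gene body. A gene assigned to a region is its nearest neighbour and is not shown to be regulated from it. The 15 gene lists cover androgen-induced and androgen-repressed genes, the cell cycle, cell cycle inhibitors, luminal transcription factors, lipid and sterol synthesis, polyamine synthesis, glycolysis and mitochondria, the unfolded protein response and androgen inactivation. They also cover basal, stromal, immune and neuroendocrine markers and housekeeping genes. For each list, the number of genes with at least 1 called region was set beside 10000 random lists matched on the number of tested regions per gene, drawn from the 200 nearest genes in that order.

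Named regions followed a rule. For 10 nM against vehicle and against low doses, they are the 6 largest rises and 6 largest falls among called regions where every library of 1 group lay above every library of the other, 1 per gene. For the low doses against vehicle and the line difference, the 5 largest each way were taken, with the separation for the line difference required in the line of the larger change. Androgen-induced genes were named by their called region of smallest p, up to 15 per line, and every other list by 3 genes per line. KLK3, TMPRSS2, FKBP5 and MYC were always given, by the region of smallest p at 10 nM. Some genes that met these rules are not reported here. After the data were seen, many of the largest changes proved to lie at the border of a neighbouring peak, so the rule was also run among regions called both with an overlap of 1 bp and with the peak covering the region's centre base, in order of the smaller of both differences.

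Comparisons of library summaries used exact permutation tests, whose smallest possible p for 3 against 3 is 0.1, and correlations with dose order used 100000 permutations. The mean value per library was also taken over regions called at 10 nM in the other line, so that the regions were chosen on other libraries. Alternatives covered the length of the lists, the peak threshold, the ranking by fold enrichment, the overlap, the filter, normal scores, presence alone, the replicate number as a block, the fit without trend or robust moderation, the groups in the fit, the distance to a gene (25 kb, or 1 kb of a gene end) and each library left out in turn. Alternatives chosen after seeing the data were the background pileup or the median fold enrichment as a covariate, the recovered pileup at regions with a peak in all 15 libraries, the ranks at those same regions, the libraries of 1 replicate number left out, separate low-dose libraries for each contrast, and the share of a list's regions. The limma fit was tested on simulated data, drawn from each line's own region means and residual spread with known changes added to the 10 nM libraries. No motifs were searched, because no genome sequence was used here. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.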

Results

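Open chromatin was profiled in LNCaP, an androgen-sensitive prostate cancer line, and in VCaP, a prostate cancer line known to carry a fusion of TMPRSS2 with ERG. The 30 libraries formed 10 groups of 3, with vehicle, 3 low doses and 10 nM of the synthetic androgen R1881 in each line. The study's stated interest is the chromatin response to low against high androgen, set beside a growth response that is not linear with dose. Peak lists held 135254 to 223998 entries in LNCaP and 105034 to 170787 in VCaP. The number of reads behind them is unknown. The recovered background pileup, a measure of relative depth, ran from 3.06 to 5.26 in LNCaP. In VCaP it was 1.14 and 1.09 in vehicle replicates 1 and 2, and 1.79 to 2.74 in the other libraries. A peak was listed at 309379 regions in LNCaP and at 312145 in VCaP, and 63063 and 39933 of these had one in all 15 libraries. Spearman's rho between replicates of a group had a median of 0.821 in LNCaP and 0.773 in VCaP, against 0.762 and 0.715 between groups.

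Strong peaks became more numerous with androgen dose in LNCaP. Entries with a −log10 q of at least 5 numbered 77844 ± 18474 (SD, n = 3) with vehicle and 138679 ± 19453 at 10 nM, and Pearson's r with dose order over the 15 libraries was 0.808 (permutation adjusted p = 0.00434, 14 relations computed; Spearman's rho 0.873, adjusted p = 0.00098). Without the 2 libraries farthest from the median dose order, r was 0.781. The covered genome rose from 73.2 ± 6.08 to 108 ± 19.1 Mb (r = 0.654, adjusted p = 0.0284). The median peak width rose from 440 to 534 bp (r = 0.712, adjusted p = 0.0147), a relation that with entries of −log10 q of at least 5 had r = 0.331 and did not pass. Of the regions with a peak in a library's shortened list, the share within 1 kb of a gene end fell from 15.9 to 15.3% (r = −0.680, adjusted p = 0.0227). LNCaP background pileup showed r = 0.186 (adjusted p = 0.586), total entries r = 0.498 and median fold enrichment r = 0.513 (both adjusted p = 0.115). In VCaP, background pileup alone passed by r (0.629, adjusted p = 0.0284), though not by rho (0.535, adjusted p = 0.102).

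At 10 nM in LNCaP, sites at classic androgen target genes that had no listed peak with vehicle ranked among each library's strongest. A region 0.482 kb outside KLK3, which encodes prostate-specific antigen (chromosome 19, 50860996 to 50861496), went from 0 to 89.7 ± 3.4 percentile points (SD, n = 3; adjusted p = 7.33e-09). A site within FKBP5, a co-chaperone of steroid receptors (chromosome 6, 35610808 to 35611308), went from 0 to 94.1 ± 2.33. At a site 58.0 kb from the oncogene MYC (chromosome 8, 127800656 to 127801156) the value rose from 8.44 ± 8.54 to 54.4 ± 11.4. The site chosen for TMPRSS2, a serine protease gene (chromosome 21, 41506936 to 41507436), fell from 68.2 ± 5.16 to 18.7 ± 10.5 (adjusted p = 0.000542). TMPRSS2 also had 8 regions that rose, and 3 that fell, of 37 tested, so a fall at its site of smallest p does not describe the gene. That fall was not called with all peaks as deposited, with the 50000 strongest peaks or with pileups at regions with a peak in all 15 libraries. The MYC rise was not called when peaks were ranked by fold enrichment.

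Of 186870 regions tested, 45036 passed in this comparison, 27630 higher and 17406 lower at 10 nM, with median differences of 43.1 and −33.2 points. Regions within 1 kb of a gene end made up 13.2% of those tested, 2.60% of the higher and 8.81% of the lower ones. With all peaks as deposited the split was 41132 higher and 7419 lower. With pileups and with ranks at regions that have a peak in all 15 libraries, lower regions outnumbered higher ones (6453 against 7888, and 5603 against 9719). That filter leaves out every region without a listed peak in 1 of the groups. Of such regions, 18559 had a peak in all 10 nM and no vehicle libraries, and 4536 the other way. The split at the remaining regions therefore does not weigh the directions over all regions. The pileups were centred on each library's median, so lower there is relative to the library's typical region. A loss of signal is not shown by it.

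The largest rises by the naming rule lay near CYB561D1, SMIM41, SNX25, ATP6V0D1, LOC124900752 and POTEC, each from 0 to between 98.4 and 99.6 points. SNX25, a sorting nexin, alone of these kept its call when a peak had to cover the region's centre base, where CYB561D1, SMIM41, LOC124900752 and POTEC were not tested, and ATP6V0D1 lost its call without any 1 of the 6 libraries compared. The largest falls were at ANKRA2, DDC, RABL3, SOS2, PPHLN1 and ZNF586, by 90.5 to 93.6 points in size, of which DDC, an enzyme of dopamine and serotonin synthesis, and RABL3 kept their calls in that way. SOS2 read 5.41 points in the opposite direction with the centre base covered. Among regions called both with an overlap of 1 bp and with the centre base covered (called both ways, a choice made after seeing the data), the largest rises were at SNX25 (chromosome 4, 185350151 to 185350651), CTTNBP2, SLC9A9, ZDHHC21, MYBL1 and PLEKHG3, to between 97.2 and 99.1 points. The largest falls were at DDC (chromosome 7, 50489541 to 50490041; from 91.7 ± 1.66 to 0), RABL3, NDUFB4, TMEM117, CSMD1 and C12orf42.

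Of 50 measured androgen-induced genes in LNCaP, 44 had a region that rose and 28 a region that fell at 10 nM (44 and 31 adjusted over the list alone). Random lists of genes with as many regions gave 37.7 rising genes (permutation p = 0.0164), which did not pass over 120 tests (adjusted p = 0.492). Named rises were at FKBP5, KLK3, NDRG1, TRPM8, TPD52, CHRNA2, MAF, PMEPA1, IQGAP2, RAB4A and ALDH1A3, and named falls at STEAP1, STEAP2 and ZBTB16. The cation channel gene TRPM8 went from 11.5 ± 10.5 to 81.6 ± 2.43, and the metalloreductase gene STEAP2 from 90.8 ± 1.68 to 16.4 ± 13 at a site 11.3 kb away. Ranking by fold enrichment ended the calls at NDRG1 and ALDH1A3, the latter at −1.37 points. Within 1 kb of a gene end, 10 of 46 induced genes rose against 2.52 for random lists (adjusted p = 0.016). Of androgen-repressed genes, 12 of 16 had a rising and 13 a falling region (12 and 13 adjusted over the list alone), with falls at PRUNE2 and CDH2, the N-cadherin gene, and a rise at MET, a receptor tyrosine kinase. Near gene ends 8 of 13 repressed genes fell against 1.41 (adjusted p = 0.016). Those falls, named after their values were seen, included BCHE (64.0 to 0), UGT2B15 (66.0 to 39.95) and MYC (76.2 to 52.8, not called with the centre base covered). Others were smaller and left the site high in rank, at PRUNE2 (90.7 to 82.3), CCN3 (92.1 to 82.9) and HES6 (86.3 to 77.2). OPRK1 went from 78.8 to 63.5 and was not called with the centre base covered.

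Growth-related lists had regions called both ways in LNCaP, and none of these lists passed against random lists. For 50 cell cycle genes, 14 had a rising and 18 a falling region (13 and 15 adjusted over the list alone), with CCND1, the cyclin D1 gene, falling from 96.0 ± 0.508 to 81.9 ± 2.12 at an intragenic site while CDK6 and MKI67 sites rose, MKI67 not tested with the centre base covered. For 20 cell cycle inhibitors the counts were 12 and 12 (12 and 12 adjusted over the list alone), with rises at BTG1, E2F7 and GADD45G, a growth arrest gene whose region 15.3 kb away went from 0 to 94.7 ± 2.26. Luminal transcription factors had 25 rising and 27 falling genes of 30 (25 and 27 adjusted over the list alone; falling, random mean 21.8, permutation p = 0.0148, adjusted p = 0.492). GRHL2, a grainyhead factor of epithelia, rose from 0 to 85 ± 1.72 and NFIB from 27.4 ± 6.82 to 88.1 ± 4.39.

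Metabolic lists also had regions called both ways in LNCaP. Lipid and sterol synthesis had 19 rising and 20 falling genes of 32 (21 and 21 adjusted over the list alone), with named rises at SOAT1, ELOVL5 and ELOVL7, ELOVL5 not when ranked by fold enrichment. Polyamine synthesis had 5 and 6 of 11 (5 and 4 adjusted over the list alone), with rises at SMOX, spermine oxidase, from 0 to 71.3 ± 1.29, and at ODC1, ornithine decarboxylase, from 30.7 ± 3.14 to 84.1 ± 2.88, and a fall at SMS. Glycolysis and mitochondria had 14 and 11 of 20 (14 and 11 adjusted over the list alone), where the coactivator gene PPARGC1A rose from 0 to 91.3 ± 1.62, with PPARGC1B and PDK4 rising as well. The unfolded protein response had 9 and 9 of 17 (9 and 9 adjusted over the list alone), with falls near EDEM1 and in ATF6 and a rise near CREB3L2. Androgen inactivation had 10 and 6 of 18 (10 and 7 adjusted over the list alone), with rises at HSD17B4, HSD17B6 and SRD5A1, which makes the stronger androgen dihydrotestosterone and was not called when ranked by fold enrichment. None of these lists passed against random lists.

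In LNCaP, regions near markers of other cell types and housekeeping genes were also called, but none of these lists passed against random lists. By share of regions called higher, basal markers had 18.0% against 13.9% in random lists (permutation adjusted p = 0.871 over 60 tests). Neuroendocrine markers had 15.2% against 12.7% (adjusted p = 0.871) and housekeeping genes 8.55% against 13.2% (adjusted p = 0.6). Basal markers had 4 rising and 2 falling genes of 9 (4 and 2 adjusted over the list alone), with rises near TP63, DSC3 and S100A2. Stromal markers had 3 and 2 of 9 (2 and 2 adjusted over the list alone; COL1A2 and COL3A1 fell, and the rise at ACTA2 ended when single libraries were left out and with the stricter peak threshold). Immune markers had 3 and 4 of 8 (3 and 4 adjusted over the list alone; ITGAM and CD3E fell and PTPRC rose), and neuroendocrine markers 7 and 5 of 12 (7 and 7 adjusted over the list alone; SCG2 and SOX2 rose and NCAM1 fell). Housekeeping genes had 7 and 5 of 18 (7 and 5 adjusted over the list alone; PGK1 and ACTB rose and YWHAZ fell, YWHAZ reading 3.12 points higher with an overlap of 250 bp). Presence of a peak within 1 kb of a gene end averaged 18 of 18 housekeeping, 24 to 26.3 of 30 luminal and 10.7 to 11 of 12 neuroendocrine genes per group over both lines. It averaged 4 to 5.33 of 9 basal, 2.67 to 4.33 of 10 stromal and 1.67 to 3.33 of 11 immune genes.

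**Figure D1:**
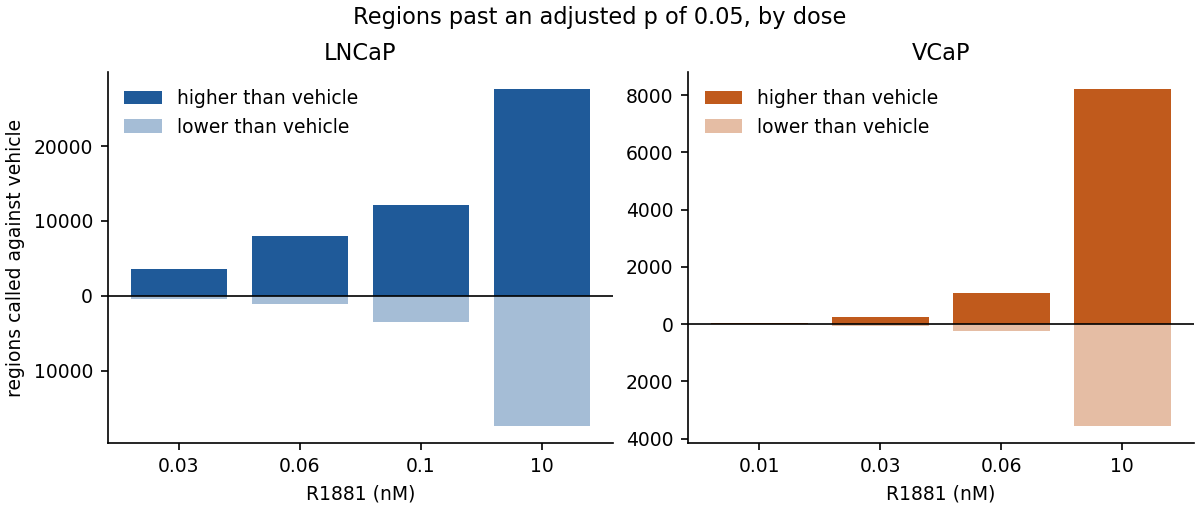
Regions called against vehicle at each R1881 dose (nM, ordered categories spaced evenly), with higher regions drawn above 0 and lower regions below it, for LNCaP and VCaP on different vertical scales. LNCaP counts went from 4013 at 0.03 nM to 45036 at 10 nM and VCaP counts from 43 at 0.01 nM to 11769 at 10 nM.

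Low androgen already raised the KLK3 and FKBP5 sites in LNCaP, which bears on the question of how low and high doses differ. KLK3 rose through 60.03 ± 2.61, 80.6 ± 4.67 and 87.5 ± 2.2 at 0.03, 0.06 and 0.1 nM, and FKBP5 through 62.6 ± 6.69, 84.5 ± 1.49 and 89.6 ± 2.24. The GADD45G region read 0, 39.4 and 73.7 at these doses. Regions called against vehicle numbered 4013 at 0.03 nM (3549 higher, 464 lower), 8998 at 0.06 nM (7941 and 1057) and 15682 at 0.1 nM (12151 and 3531). The lower counts were 2327, 3648 and 7315 without vehicle replicate 5 and 223, 310 and 1150 with all peaks as deposited, so the number of falls at low doses is loose. Without vehicle replicate 5, the 0.03 nM count was 6300, and with only the groups compared in the limma fit it was 0, with 8588 regions at an unadjusted p under 0.05, where 8430 are expected with no change. With only the groups compared the counts at 0.06 and 0.1 nM were 2240 and 8117.

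For the 3 low doses together against vehicle, LNCaP had 9851 higher and 2661 lower regions (11096 and 871 with all peaks as deposited, 9460 and 1174 with normal scores, 8631 and 5471 without vehicle replicate 5). Among the largest rises were CACNG4, a calcium channel subunit gene (0 to 89.6 ± 3.84, n = 3 and 9), SNX25, OTOL1 and CTAGE1, each by 88.3 to 89.6 points. The largest falls were at FBXO31, SKIC3, SOS2, BBX and C5orf22, by 74.7 to 79.8 points in size, and of these SKIC3 kept its call with the centre base covered, while SOS2 read 7.11 points higher and BBX was not tested. The BBX call ended without vehicle replicate 3 or 4, and those at SKIC3 and SOS2 with normal scores. Among regions called both ways, the largest falls were at CEP350, SPOCK1, KCNA4, OLFML3 and CCDC34, by 55.3 to 63.4 points in size, of which CEP350, OLFML3 and CCDC34 were not called with an overlap of 250 bp, OLFML3 also not with the stricter peak threshold and CCDC34 not with normal scores.

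From low doses to 10 nM, LNCaP peaks entered the lists at some regions and left them at others. A site in LEKR1 (chromosome 3, 156906261 to 156906761) read 0 in all low-dose groups and 88.6 ± 1.22 at 10 nM (adjusted p = 6.40e-07), and the DDC site fell from 82.6 ± 10.7 over the 9 low-dose libraries to 0. Other named rises were at MYL10, RASSF3, LOC124903162, ST18, a zinc finger gene, and MC2R, the corticotropin receptor gene, and falls at TMEM50B, STAU2, ZNF586, PRKG1 and PARD3B. Of these, ST18 and MC2R kept their calls with the centre base covered, where MYL10, RASSF3 and LOC124903162 were not tested. Regions called both ways added rises at SLC6A3, VPS26B and PDE8B and falls at TMEM117, ST8SIA3, ADGRV1, C12orf42 and THRB, a thyroid hormone receptor gene. In total 15667 regions were higher and 10370 lower at 10 nM than at low doses. The count of 26037 became 14100 without 10 nM replicate 5 and 14902 without 10 nM replicate 4, and which direction was more frequent depended on the setting. Higher and lower regions numbered 22949 and 4268 with all peaks as deposited, 6169 and 9931 with a peak in at least 8 libraries, 8169 and 10390 without the libraries numbered 5, and 1518 and 7372 with ranks or 2919 and 4402 with pileups at regions with a peak in all 15 libraries. Regions listed only at 10 nM cannot pass a filter of 8 or 15 libraries. Without the libraries numbered 5, too few 10 nM libraries remain for such regions to pass the filter of 3. These splits thus leave out rises from 0 and do not weigh the directions over all regions.

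Of LNCaP regions raised at low doses, 2419 were higher still at 10 nM and 97 were lower at 10 nM than at low doses. Independent lists would give 826 and 547, and 99 regroupings of the libraries gave at most 0 and 8, but the low-dose libraries enter each of these contrasts, so neither is the count expected with no change. With the replicate number as a block the 97 became 207. The 2419 became 872, 981 and 1253 without 10 nM replicate 5, 4 or 3, and the 97 became 36 and 40 without 10 nM replicate 5 or 4, 156 without 0.03 nM replicate 5 and 24 with all peaks as deposited. With separate low-dose libraries for each contrast the counts were 153 and 135 in place of 2419, and 28 and 29 in place of 97. Regions lowered at low doses were lower still at 10 nM in 500 cases, against 148 for independent lists, and higher in 22, against 223. The 99 regroupings gave at most 0 and 12, and with separate low-dose libraries the 500 became 34 and 19 and the 22 became 2 and 1. For gene groups between low doses and 10 nM, luminal transcription factors had 17 rising and 24 falling genes (falling, random mean 17.4, permutation p = 0.0058), androgen-induced genes 31 and 30, androgen-repressed genes 9 and 12, cell cycle genes 9 and 15 and cell cycle inhibitors 11 and 12. Lipid and sterol synthesis had 17 and 15, polyamine synthesis 4 and 5, glycolysis and mitochondria 10 and 8, the unfolded protein response 8 and 7 and androgen inactivation 9 and 4. Markers had 4 and 1 (basal), 1 and 2 (stromal), 1 and 3 (immune), 3 and 1 (neuroendocrine) and 5 and 4 (housekeeping). No list passed over the 120 tests (lowest adjusted p = 0.492), but within 1 kb of a gene end 11 of 46 androgen-induced genes fell against 3.45 (adjusted p = 0.030), as did 7 of 13 repressed genes against 0.875 (adjusted p = 0.016).

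**Figure D2:**
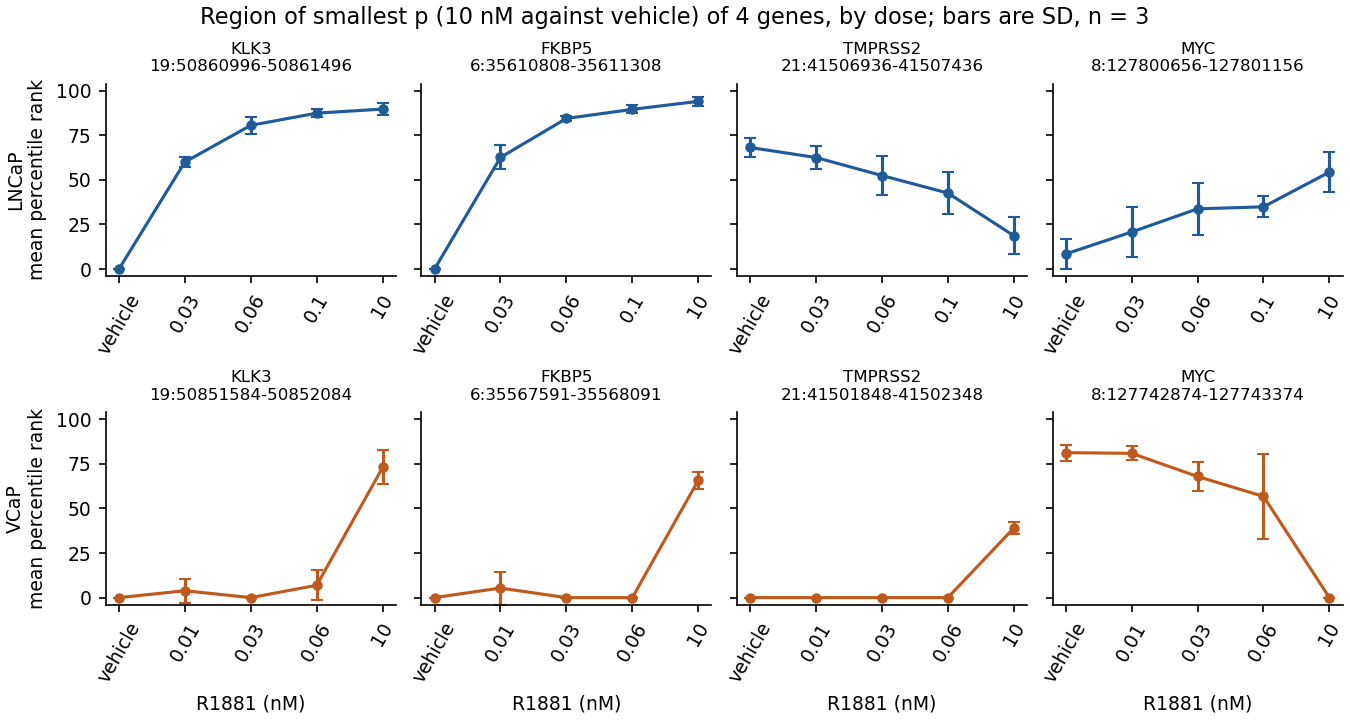
Mean percentile rank (0 to 100) of the region of smallest p at 10 nM for 4 genes by R1881 dose (nM, ordered categories spaced evenly), with LNCaP above and VCaP below; bars are the SD, n = 3, and the region differs between the lines. FKBP5 in LNCaP reached 62.6 at 0.03 nM, while KLK3 in VCaP read 6.92 at 0.06 nM and 73.0 at 10 nM.

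At 10 nM in VCaP, regions near KLK3, FKBP5 and TMPRSS2 that were not listed with vehicle entered the lists, and a region at MYC left them. A region 3.08 kb from KLK3 (chromosome 19, 50851584 to 50852084) went from 0 to 73.0 ± 9.56 points (SD, n = 3; adjusted p = 0.000674), one 5.75 kb from FKBP5 (chromosome 6, 35567591 to 35568091) from 0 to 65.7 ± 4.75 and one inside TMPRSS2 (chromosome 21, 41501848 to 41502348) from 0 to 39 ± 3.28. A region 0.173 kb from MYC (chromosome 8, 127742874 to 127743374) fell from 81.3 ± 4.56 to 0 (adjusted p = 0.000549; not called with the stricter peak threshold, at −19.5 points). Of 141802 regions tested, 8211 were higher and 3558 lower, by medians of 54.0 and −46.1 points. Within 1 kb of a gene end lay 16.8% of tested, 3.11% of higher and 5.45% of lower regions. The split was 9442 and 2059 with all peaks as deposited and 771 and 1219 with ranks at regions with a peak in all 15 libraries. The latter leaves out regions without a listed peak in 1 of the groups. Of these, 6962 had a peak in all 10 nM and no vehicle libraries, and 2289 the other way. The count of 11769 became 6645 without 10 nM replicate 1, 7226 without 10 nM replicate 4, and 1459 with background pileup as a covariate, which also ended the call at TMPRSS2.

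The largest VCaP rises were at PLAAT3, ZNF695, EPB41L4B, DROSHA, CHL1, a neural adhesion gene, and IFNAR2-IL10RB, from 0 to between 96.1 and 99.2 points, all also with the centre base covered but DROSHA, which was not tested that way. The largest falls were at DYRK1B, LOC124906262, SNRPF, FBXL15, KCNQ3, a potassium channel gene, and NEB, and of these KCNQ3 and NEB kept their calls with the centre base covered, while LOC124906262, SNRPF and FBXL15 also lost theirs when single libraries were left out. Regions called both ways added a rise at ZHX2 and falls at SOAT1, NFE2L2, LOC107986837 and PRKG1. The calls at the rises PLAAT3, DROSHA and IFNAR2-IL10RB and the falls LOC124906262, SNRPF, FBXL15 and SOAT1 ended with background pileup as a covariate, and those at SNRPF, FBXL15, LOC107986837 and PRKG1 with the stricter peak threshold.

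Of 50 androgen-induced genes in VCaP, 26 had a rising and 13 a falling region (33 and 16 adjusted over the list alone). Rises were named at LIFR, RAB4A, HPGD, KLK3, FKBP5, TPD52, ZBTB10, TMPRSS2, STEAP4, TRPM8, ELL2, KLK2 and ZBTB16, and falls at NDRG1 and STEAP2, and TPD52 went from 21.1 ± 31.2 to 90.9 ± 2.25. The RAB4A and KLK2 regions were not tested with the centre base covered. Calls at TMPRSS2, KLK2 and ZBTB16 ended when ranked by fold enrichment, and those at ZBTB10, STEAP4, TRPM8, ELL2, KLK2 and STEAP2 with background pileup as a covariate. The STEAP2 call also ended with the stricter peak threshold, and those at TMPRSS2, STEAP2, KLK2 and ZBTB16 with only the groups compared. Androgen-repressed genes had 6 and 6 of 16 (6 and 6 adjusted over the list alone), with a rise at CDH2. Cell cycle genes had 4 and 3 of 50 (3 and 2 adjusted over the list alone), with rises at CENPF and CDK6 and a fall at CDK1, and inhibitors 8 and 3 of 20 (8 and 4 adjusted over the list alone), with rises at GADD45G, from 0 to 88.7 ± 1.37, and KLF4 and a fall at BTG2. Luminal factors had 14 and 8 of 30 (14 and 7 adjusted over the list alone), with rises at NCOA2, GRHL2 and GATA3, the last from 0 to 90.8 ± 1.43.

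In the other VCaP groups, lipid and sterol synthesis had 12 and 8 of 32 (14 and 8 adjusted over the list alone), with rises at SCARB1, a lipoprotein receptor gene, and ACACA and a fall at SOAT1. Polyamine synthesis had 1 and 1 of 11 (0 and 0 adjusted over the list alone), SMOX rising from 0 to 66 ± 20.02, not without 10 nM replicate 1 or 4, and SMS falling by 15.6 points, a call kept in 7 of 31 alternatives. Glycolysis and mitochondria had 11 and 4 of 20 (11 and 5 adjusted over the list alone; PPARGC1B and SLC2A1, a glucose transporter gene, rose and PPARGC1A fell). The unfolded protein response had 4 and 4 of 17 (4 and 4 adjusted over the list alone; CREB3L2 and ERN1 rose, and EDEM1 fell from 79.5 ± 4.03 to 0). Androgen inactivation had 5 and 3 of 18 (5 and 3 adjusted over the list alone; UGT2B28, SRD5A1 and CYP3A4 rose). Basal markers had 2 and 1 of 9 (3 and 1 adjusted over the list alone; DSC3 rose and TP63 fell), stromal 1 and 1 of 8 (1 and 1 adjusted over the list alone; COL1A2 rose), immune 0 and 0 of 6, neuroendocrine 4 and 2 of 12 (4 and 3 adjusted over the list alone; NCAM1, SCG3 and NEUROD1 rose) and housekeeping 2 and 1 of 18 (1 and 0 adjusted over the list alone; GUSB and YWHAZ rose, YWHAZ not without 10 nM replicates 1 or 2 or vehicle replicate 4). None of these passed against random lists, and the calls at CENPF, CDK6, CDK1, GADD45G, KLF4, SOAT1, ACACA, SMOX, SMS, PPARGC1A, PPARGC1B, SLC2A1, ERN1, SRD5A1, CYP3A4, DSC3, COL1A2, SCG3 and NEUROD1 ended with background pileup as a covariate. Those at SCARB1, SCG3, SMS and YWHAZ ended with the stricter peak threshold.

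Few regions were called at low doses in VCaP. The largest low-dose rises were at SPOCK1, a proteoglycan gene, from 0 to 83.1 ± 9.12 (n = 3 and 9, adjusted p = 3.69e-07), ILRUN, LLPH, ZDHHC21 and ZNF280C, all called with the centre base covered. With the stricter peak threshold the calls at SPOCK1, LLPH, ZDHHC21 and ZNF280C ended, ZNF280C at 8.13 points, and LLPH also lost its call with an overlap of 250 bp and with background pileup as a covariate. The ZDHHC21 region read 59.8 ± 14.4, 88.7 ± 0.588 and 92.7 ± 1.39 at 0.01, 0.03 and 0.06 nM. Falls were named at TBC1D31, MAML2, PRKCE, REEP1 and WNT5A, with calls at REEP1 and WNT5A lost with the centre base covered and TBC1D31, MAML2 and PRKCE not tested that way, and among regions called both ways at TMEM182, SCN3A, WWTR1 and NUP107, of which WWTR1 and NUP107 were lost when single libraries were left out, as was PRKCE. Background pileup as a covariate ended the calls at TBC1D31, PRKCE, REEP1, WNT5A, TMEM182, SCN3A, WWTR1 and NUP107, and normal scores ended all of these but PRKCE. Regions called numbered 43 at 0.01 nM (38 higher, 5 lower), 311 at 0.03 nM (263 and 48), 1336 at 0.06 nM (1105 and 231) and 855 for the low doses together (611 and 244; 1460 and 66 with all peaks as deposited). With only the groups compared, limma called 1, 3 and 0 regions at the single doses and 250 for all 3, where the 0 went with 12488 at an unadjusted p under 0.05 and 6838 expected with no change. With background pileup as a covariate the counts were 16, 70, 153 and 123. Leaving out single libraries moved the first counts to between 12 and 438, 101 and 1019, 244 and 1956, and 480 and 2012. The highest of these at 0.01 nM, at 0.03 nM and for the low doses together came without vehicle replicate 4, whose background of 2.11 was the highest in its group.

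From low doses to 10 nM in VCaP, PTPN3, a tyrosine phosphatase gene, rose from 0 to 91.0 ± 1.23 (adjusted p = 3.47e-05), and PRKG1, a cGMP-dependent kinase gene, fell from 73.8 ± 9.45 to 0, though by −8.27 points and without a call with the stricter peak threshold. Further rises were at MOB3B, MRPS9, TMEM98 and EPN2 and falls at GSPT1, LMLN, ERC2, PPFIBP2 and FRRS1L, with calls at GSPT1, LMLN and PPFIBP2 lost with the centre base covered and MOB3B and TMEM98 not tested that way. Regions called both ways added CHKA among the rises and LPP and PRSS23 among the falls. The calls at LMLN, ERC2, PPFIBP2, FRRS1L, LPP and PRSS23 also ended with the stricter peak threshold. In all 5486 regions were higher and 1458 lower, 6944 together, and 3613 without 10 nM replicate 1 and 4004 without 10 nM replicate 4. With ranks at regions with a peak in all 15 libraries the split was 41 and 668, but regions listed only at 10 nM cannot enter there. Androgen-induced genes had 24 rising and 9 falling genes, repressed genes 3 and 6 (falling, random mean 2.23, permutation p = 0.016), cell cycle 2 and 2, inhibitors 7 and 1, luminal factors 14 and 5, lipid and sterol synthesis 9 and 3, polyamine synthesis 0 and 0, glycolysis and mitochondria 7 and 2, the unfolded protein response 3 and 2 and androgen inactivation 4 and 2. Markers had 2 and 1 (basal), 1 and 0 (stromal), 0 and 0 (immune), 3 and 0 (neuroendocrine) and 1 and 0 (housekeeping). None passed over the 120 tests.

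The lines were compared to ask whether 10 nM acted on the same sites. At the VCaP sites of FKBP5 and MYC the LNCaP change minus the VCaP change was −33.8 points (adjusted p = 0.0114) and 76.5 points (adjusted p = 0.00287), and in LNCaP the MYC site read 16.2 ± 9.23 with vehicle, 39.6 ± 9.45 at 0.1 nM and 11.4 ± 9.05 at 10 nM. Ranks end at 0, so from 16.2 this MYC site could not fall as far in LNCaP as it did in VCaP. The difference did not pass at the VCaP sites of KLK3 (−4.92, adjusted p = 0.936) and TMPRSS2 (−10.5, adjusted p = 0.564), or at the LNCaP sites of TMPRSS2 (−25.0, adjusted p = 0.345) and MYC (19.9, adjusted p = 0.553).

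Of 107845 regions tested, 2464 differed between the lines in their 10 nM change, 1560 with the LNCaP change more positive and 904 with it more negative. Among the largest were PSMB3, LOC124906262, RPL5 and SPDEF, a prostate epithelial ETS factor, on the positive side, and PPFIA1, SETD2, a histone methyltransferase gene, SOS2, DROSHA and TMEM42 on the negative. SETD2 (chromosome 3, 47035036 to 47035536) went from 80.1 to 20.002 in LNCaP and from 9.94 to 87.7 in VCaP (adjusted p = 0.000133). Of these regions, PSMB3, PPFIA1 and SETD2 kept their calls with the centre base covered, RPL5, SPDEF and DROSHA were not tested that way, and PSMB3, LOC124906262, RPL5, DROSHA and TMEM42 lost theirs when single libraries were left out. Regions called both ways added RND3, CDKL4, PRRC2C and HACE1 on the positive side and SASH1, INSYN2B, lost without VCaP 10 nM replicate 1, and ARID3B on the negative. Background pileup as a covariate ended the calls at LOC124906262, RPL5, SOS2, DROSHA, TMEM42, HACE1, SASH1 and ARID3B, and normal scores those at PSMB3, LOC124906262, RPL5, PPFIA1, SOS2, DROSHA, HACE1, SASH1, INSYN2B and ARID3B. Among regions higher in both lines 385 of 5300 differed, and among those lower in both 74 of 1557. For regions called in LNCaP and not in VCaP, 1106 of 10944 higher and 423 of 9344 lower ones differed. For regions called in VCaP and not in LNCaP, 218 of 1095 higher and 174 of 1296 lower ones differed. The count of 2464 became 1270 without LNCaP 10 nM replicate 5, 1390 without LNCaP 10 nM replicate 4 and 1579 without VCaP 10 nM replicate 2.

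Regions chosen in one line moved with dose in the other. At the 8211 regions higher in VCaP, LNCaP values were 14.5 ± 0.900, 23.9 ± 1.72, 32.1 ± 2.30, 38.0 ± 2.24 and 51.8 ± 1.60 from vehicle to 10 nM. There r was 0.985 (permutation p = 1e-05, the smallest that the permutations can give, rho = 0.982), and 0.982 without LNCaP 10 nM replicates 3 and 4. At the 27630 regions higher in LNCaP, VCaP values were 14.8 ± 2.53, 16.9 ± 3.98, 19.2 ± 4.44, 25.2 ± 3.99 and 33.1 ± 2.2. Their r was 0.879 (permutation p = 5e-05, rho = 0.884), and 0.829 without VCaP 10 nM replicates 1 and 2. Regions lower in the other line fell with dose in LNCaP (49.2 to 27.9, r = −0.907, rho = −0.895) and in VCaP (33 to 20.96, r = −0.820, permutation p = 0.00029, rho = −0.807), over 4 relations in all. Without the same 2 libraries of each line, r was −0.865 in LNCaP and −0.754 in VCaP. With all peaks as deposited these falls were smaller, from 52.4 to 40.1 in LNCaP (r = −0.739) and from 35.4 to 26.2 in VCaP (r = −0.664). A region that keeps its signal while others rise also falls in rank, so these falls do not show a loss of signal. At 1558 VCaP-lower regions with a peak in all 15 LNCaP libraries, pileup over background changed by a median log2 of 0.07 (SD 0.66 over regions). Within replicate numbers, LNCaP rises at 10 nM were 35.6 to 38.3 points and VCaP rises 17.3 to 19.1. Against vehicle, each higher-region mean at 10 nM had an exact p of 0.1, the smallest that 3 against 3 allows.

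**Figure D3:**
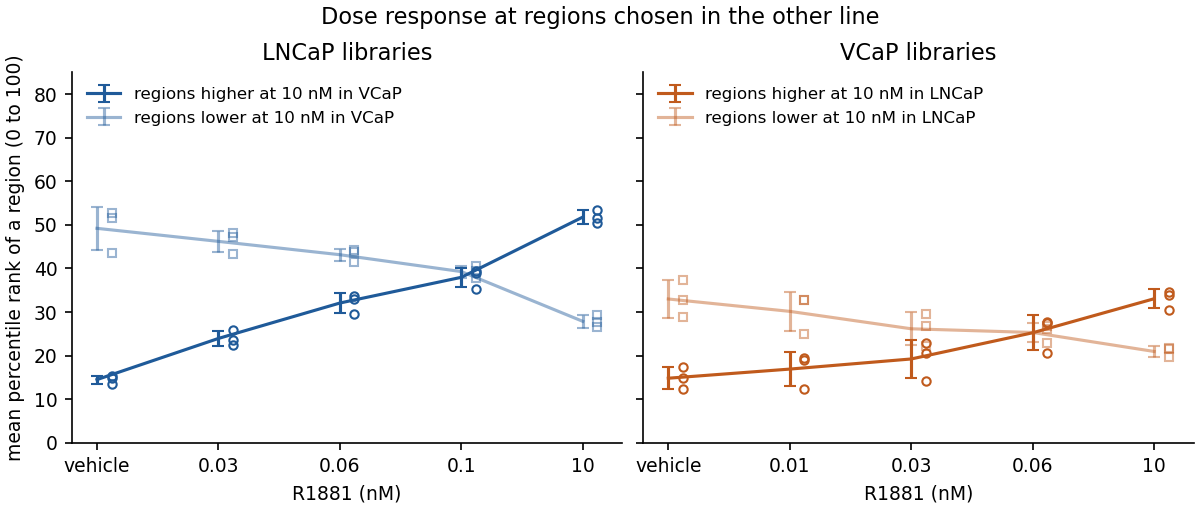
Mean percentile rank (0 to 100) by R1881 dose (nM, ordered categories spaced evenly) over regions called at 10 nM in the other line, with lines joining group means, bars for the SD (n = 3) and points for single libraries. LNCaP values at regions higher in VCaP rose from 14.5 to 51.8, and VCaP values at regions higher in LNCaP from 14.8 to 33.1.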

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

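The regroupings, the fit with background pileup as a covariate and the test over the treated VCaP libraries were chosen after the results were seen, while the test on left-out 10 nM libraries was planned before its result. The 10 nM change differed between LNCaP and VCaP at 2464 regions by a test of the difference itself. Of 100 splits that shuffled the groups within each line, 1, the real one, gave as many regions (highest other 835). Such splits take the dose effect out of both lines and spread 10 nM libraries over other groups. They therefore cannot say how many regions would pass if both lines changed alike.

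At single genes the same test passed at a pair of VCaP sites. At a site near FKBP5 the LNCaP change minus the VCaP change was −33.82 points, as the site rose in both lines and more in VCaP. At a site next to MYC, which had no listed peak at 10 nM in VCaP, it was 76.52 points, since LNCaP hardly changed there.

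One pattern behind such differences is the set of VCaP regions that were higher at 10 nM, since vehicle replicates 1 and 2 had the lowest background pileup of the line. When regions were called from 2 of the 10 nM libraries, the library left out stood above the low-dose libraries, which are of like depth, by medians of 40.7, 30.99 and 36.1 points, while single low-dose libraries reached 18.7 at most. Lower depth of vehicle libraries as the whole cause of the rises is argued against by that, and by r = 0.8752 with dose over the 12 treated libraries at regions chosen in LNCaP (permutation p = 0.00035). How many regions changed stays open, because the count was 1459 with background pileup as a covariate, and background and vehicle membership cannot be told apart well in these libraries (r = −0.754). An androgen effect remains a hypothesis for these regions, and depth may add to their number.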

How the results depend on the processing

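The covariates, the analyses at regions with a peak in all 15 libraries, the left-out replicate numbers, the separate low-dose libraries and the share of a list's regions were chosen after the data were seen. For the counts and tests of the comparisons, 912 alternative values stayed within 1.5 times or on their side of the threshold, 161 moved, 6 became stronger and 1 weaker. For named regions 6467 values kept direction and call, 416 lost the call, 10 gained it and 6 reversed. Unless stated, the cause was not tested.

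LNCaP counts are given in the order 0.03, 0.06, 0.1 and 10 nM against vehicle, 10 nM against low doses and low doses against vehicle. With the 50000 strongest peaks, which leave fewer regions, they were 1834, 4590, 7710, 19339, 11270 and 6392. With the stricter threshold they were 2135, 5278, 8894, 22310, 12929 and 7364. Recovered pileups at regions with a peak in all 15 libraries gave 1026, 3372, 6278, 14341, 7321 and 4992, and ranks there 1482, 2751, 4669, 15322, 8890 and 3904, with fewer regions tested. With only the groups compared, which leaves fewer libraries, the first 3 were 0, 2240 and 8117. A peak in at least 8 libraries gave 16100 for 10 nM against low doses. Leaving out 1 library gave 3396 to 6300, 6272 to 11399, 11098 to 18668, 33119 to 50224, 14100 to 29460 and 10223 to 14102.

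VCaP counts at 0.01 nM were 105 with all peaks as deposited, 23 with the 50000 strongest, 9 with the stricter threshold, 16 with 250 bp of overlap, 140 without trend or robust moderation, 1 with only the groups compared, 16 with background as a covariate, 4 with pileups and 7 with ranks at regions with a peak in all 15 libraries, and 107 without the libraries numbered 2. At 0.03 nM, in the same order but with normal scores in place of the 50000 strongest, they were 800, 85, 54, 80, 623, 3, 70, 206, 92 and 471. At 0.06 nM they were 2564 with all peaks, 403 with the stricter threshold, 393 with 250 bp, 313 with normal scores, 2633 without trend or robust moderation, 0 with only the groups compared (limma; 12488 at an unadjusted p under 0.05, with 6838 expected by chance), 153 with background and 2307 with median fold enrichment as a covariate, and 309 with ranks. At 10 nM they were 7789 with the 50000 strongest, 2728 with the stricter threshold, 6552 with a peak in at least 8 libraries, 7452 with normal scores, 5801 with only the groups compared, 1459 with background as a covariate, 3515 with pileups and 1990 with ranks. For 10 nM against low doses they were 4432 with the 50000 strongest, 1758 with the stricter threshold, 1544 with at least 8 libraries, 4035 with normal scores, 1322 with pileups, 709 with ranks and 4151 without the libraries numbered 2. For low doses against vehicle they were 1526 with all peaks, 189 with the stricter threshold, 363 with 250 bp, 569 without a filter, 402 with normal scores, 250 with only the groups compared, 123 with background as a covariate, 498 with pileups and 207 with ranks. Leaving out 1 library gave 12 to 438, 101 to 1019, 244 to 1956, 6645 to 12699, 3613 to 6871 and 480 to 2012. Low counts rested on many libraries, with 13 of the single omissions at 0.01 nM moving it by over 1.5 times.

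The count that differed between the lines, 2464, was 1456 with the 50000 strongest, 1203 with the stricter threshold, 1231 with 250 bp, 6887 without a filter, 1146 with at least 8 libraries, 751 with normal scores and 860 with only the groups compared, and 1270 to 2858 without 1 library. Regions raised at low doses and lower at 10 nM were 24 with all peaks, 57 without a filter, 147 without trend or robust moderation, 186 with median fold enrichment as a covariate, 39 with pileups, 28 and 29 with separate libraries, and 36 to 156 without 1 library. Regions raised and higher still were 1405 with the 50000 strongest, 1569 with the stricter threshold, 1416 with normal scores, 1198 with pileups, 1525 without the libraries numbered 5, 153 and 135 with separate libraries, which leave fewer per group, and 872 to 2810 without 1 library. Peaks in all 3 VCaP libraries at 0.03 nM or vehicle and in none of the others numbered 2515 with all peaks.

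Replicate numbers did not pair the libraries by the planned rule. In LNCaP 18 of 30 pairs of residuals with the same number correlated above 0.1 and 11 of 15 libraries agreed best with their own number, and in VCaP 22 of 30 and 15 of 15. All these correlations were positive in VCaP (0.0620 to 0.297), against −0.107 to 0.397 in LNCaP. Within LNCaP they ran from 0.0816 to 0.231 for number 3, −0.107 to 0.126 for number 4 and 0.112 to 0.397 for number 5. So VCaP libraries of a number resembled each other, as did LNCaP libraries numbered 3 and those numbered 5. The main fits and the permutation tests did not use the number. With the replicate number as a block, counts were 4510, 10591, 18435, 52436, 32228 and 14898 in LNCaP, 54, 465, 2509, 15286, 8648 and 1250 in VCaP, 4110 between the lines and 207 for regions raised at low doses and lower at 10 nM.

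Presence alone gave 0 regions in both lines by an exact trend test, whose smallest p was 0.0003996, while 32685 and 14380 had an unadjusted p under 0.05. That smallest p was reached by 1193 and 242 regions, where 1494 and 1134 would have passed the adjustment. LNCaP entries of −log10 q at least 5 rose with dose (r = 0.80809) where all entries did not pass, and median width then did not (r = 0.33059). Within 1 kb of a gene end, the lists passed in LNCaP that did not within 100 kb, with 10 androgen-induced genes higher and 8 androgen-repressed genes lower at 10 nM, and 11 induced and 7 repressed genes lower at 10 nM against low doses. By share of regions called higher the induced list passed too, at 23.142%. SOS2 reversed to 5.4117 at 10 nM and 7.1133 at low doses with 250 bp or the centre base, ALDH1A3 to −1.3667 when ranked by fold enrichment and YWHAZ to 3.1158 with 250 bp. Motif searches and their alternatives were not run. In simulated data 40 points were recovered at 27% in LNCaP and 13.5% in VCaP when added to 200 regions, and at 69.1% and 52.1% when added to 20000, so the share missed depends on how many regions change, and up to 10% of calls were false.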

Other observations

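The regroupings, the tests of pileup and of the full lists at falling LNCaP regions, the test at regions chosen in VCaP and the shares of list regions were chosen after the results were seen; the size of the fall and the residual tests of strong entries were written before theirs. Some sites followed dose in both lines. The TPD52 site read 14.9, 61.6, 78.4, 86.3 and 90.8 points from vehicle to 10 nM in LNCaP and 21.1, 60.8, 81.4, 90.1 and 90.9 in VCaP. The SMOX site read 0, 0, 0, 5.72 and 71.3 in LNCaP and 0, 3.26, 16.1, 66.9 and 66 in VCaP, and the EDEM1 site fell from 96.2 to 54.3 in LNCaP and from 79.5 to 0 in VCaP. Near gene ends, sites named after their values were seen rose in LNCaP at KLK2 (0 to 65.5), SPDEF (0 to 96.2, not tested with the centre base covered), ACSL3 (0 to 58.2) and SORD (10.7 to 49.7), and in VCaP at ABCC4 (0 to 46.2).

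Peaks present in all 3 libraries of a dose and in none of vehicle numbered 18559 at 10 nM in LNCaP, with 4536 the other way, and 6962 and 2289 in VCaP. The totals exceeded the highest of the 9 other splits of the 6 libraries (3145 and 2278), but 10 splits are too few for a share under 0.05. At 0.03 nM in LNCaP the counts were 1718 and 734 (highest other total 3571), and at 0.01 nM in VCaP 552 and 360 (highest other total 4132).

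LNCaP regions that were lower at 10 nM may partly have been displaced in lists of fixed length by rising regions. At 9515 of them with a peak in all 15 libraries, summit pileup over background changed by a median of 0.02404 on the log2 scale, with the 10 nM libraries (3.36 to 3.52) inside the range of the vehicle libraries (2.67 to 3.96), so a change in either direction is not shown. Uncalled regions changed by 0.67 and called-higher regions by 1.89, each with the 10 nM libraries (4.41 to 4.54, and 4.85 to 4.88) above all vehicle libraries (2.88 to 4.13, and 2.21 to 3.19). The median fall of −23.38 points, against −1.09 at uncalled regions, met the bound written beforehand against displacement, but that bound was wrong because these regions were chosen for their fall. Regions chosen in VCaP as lower fell by a median of −19.09 points in LNCaP, against −2.09 at regions of like rank, which a first form of the bound counted against displacement; it was tightened afterwards because a region that keeps its signal while others rise also falls in rank, and pileup over background there changed by 0.07 (SD 0.66 over regions). Of 3281 called-lower regions with a peak in all vehicle lists and in none at 10 nM, 2348 had a peak in at least 1 full list at 10 nM, which is what displacement needs. In the full lists 1871 regions, 975 of them called lower, had a peak in all vehicle libraries and in none at 10 nM, but other splits of these libraries gave up to 3174, and the shortest list at 10 nM (167378) was shorter than the longest vehicle list (174513). The DDC region was called in 30 of 30 alternatives, the full lists among them. Whether accessibility fell at these regions as a set stays open.

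The rise of strong LNCaP entries with dose was weighed against depth and the share of reads in peaks. After regression on background pileup the residuals still rose with dose (r = 0.7893, permutation p = 0.00036), and so did those of a separate regression on median fold enrichment (r = 0.6533, permutation p = 0.00981). The first test argues against depth as the whole cause. The second decides nothing on the share of reads in peaks, because the median fold enrichment of a library's listed entries is not that share. Uncalled LNCaP regions with a peak in all 15 libraries also rose in pileup over background, by a median of 0.67 on the log2 scale. There the 10 nM libraries (4.41 to 4.54) lay above all vehicle libraries (2.88 to 4.13). An effect of androgen on the number of strong sites is a hypothesis found and tested on the same libraries.

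Androgen-induced genes may have more changed regions than genes with as many regions. In LNCaP 23.14% of the list's 834 regions were higher, against 15.4% (12.6 to 18.3%) in matched random lists (permutation p = 0.0002, adjusted p = 0.012 over 60 tests), and 9.592% were lower, against 9.76%. In VCaP 9.214% were higher, against 6.40% (adjusted p = 0.27), and 2.304% lower, against 2.79%, which decides neither way.

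Regroupings of the 15 libraries of a line into 5 groups of 3 tested whether groups drawn at random give such counts. Of 100 splits, 1, the real one, called as many regions in LNCaP at 10 nM (45036, highest other 379) and at 10 nM against low doses (26037, 659), and in VCaP at 10 nM (11769, 152) and at 10 nM against low doses (6944, 2446). Counts as high as these were rare among random groups, which alone does not exclude chance. The splits did not use replicate numbers. At low doses the real split also stood alone in LNCaP at 0.03 nM (4013, 73), 0.06 nM (8998, 3404), 0.1 nM (15682, 1549) and for all low doses (12512, 5554), and in VCaP at 0.03 nM (311, 168), 0.06 nM (1336, 407) and for all low doses (855, 711), while 7 of 100 splits called as many as 43 at 0.01 nM in VCaP. These splits move 10 nM libraries into other groups, which widens the residual spread and can lower the counts of the other splits in every contrast. For low doses they decide nothing. The VCaP split with 10207 regions at 0.01 nM set the 3 libraries at 10 nM against vehicle replicates 1 and 2 and 0.01 nM replicate 2, a structure of the samples that carries the 10 nM change.

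With the 10 nM libraries kept in their group and the other 12 regrouped, 1 of 100 splits, the real one, called as many regions in LNCaP at 0.03 nM (4013, highest other 3392), 0.06 nM (8998, 5319), 0.1 nM (15682, 1508) and for all low doses (12512, 1488), and in VCaP at 0.03 nM (311, 310) and 0.06 nM (1336, 397). For all low doses in VCaP 2 of 100 splits called as many (855, 2780), and at 0.01 nM 8 of 100 did (43, 2265). At 0.03 nM in VCaP the real split led by only 1 region. The LNCaP split with 5319 regions put the 3 vehicle libraries together in another group, so it carries the low-dose change. The VCaP splits with 2780 and 2265 regions put the 0.01, 0.03 and 0.06 nM libraries numbered 2 together in 1 group, so they follow the replicate number, and with that number as a block the counts were 1250 and 54. These splits still mix libraries of different low doses, which can widen the residual spread, and the comparisons were not corrected for their number. Apart from 0.01 nM in VCaP, counts as high as the real ones were rare among them, which alone does not exclude chance. With only the groups compared limma called 0 regions at 0.03 nM in LNCaP (8588 at an unadjusted p under 0.05, 8430 expected), 3 at 0.03 nM in VCaP and 0 at 0.06 nM in VCaP (12488, 6838 expected), so calls of single regions at these doses rest on the other libraries in the fit. At regions called in the other line, means rose against vehicle by 9.44 points at 0.03 nM in LNCaP (exact p = 0.1), 4.42 at 0.03 nM in VCaP (exact p = 0.3) and 10.4 at 0.06 nM in VCaP (exact p = 0.1), where 0.1 is the smallest that 3 against 3 allows. The exact tests did not use replicate numbers, within which the VCaP rises at 0.03 nM were 1.99 to 5.74 points.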
